A study of Mus musculus with 42 samples.

How the data were processed

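Gene counts of 24 mouse joint soft tissue and 18 lymph node libraries were used, as 1 table per tissue. Per the labels' protocols, tissues were removed and flash frozen, RNA was taken from nodes with RLT and from joint soft tissue with Trizol, and libraries were made from 100 ng of total RNA with the NEBNext Ultra II RNA kit. Per the submitters' processing notes, reads were handled with fastp and STAR on the mouse build mm10, with versions not given there. The values are whole-number counts per gene as deposited by the authors, unnormalised. The counting program, its annotation, its strand setting and the handling of reads that map to several places are not given in the sources used here. Antisense and overlapping genes, and near-identical copies such as the granzymes Gzmd and Gzme, the Cd209 family, Bglap and Bglap2 and the antibody genes, are therefore uncertain.

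The joint table listed 36604 genes, none at 0 in every library, and that of the nodes 54752, of which 17552 were at 0 in every library. The tables list different genes and were tested separately. Gene identifiers were matched to symbols and positions of GENCODE M21 (mm10), for 36591 joint and 54723 node genes. Positions are 1-based on mm10. No table column was left unused.

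Groups were taken from the sample titles. No 2 libraries of a group agreed within sampling noise: the lowest chi-square per degree of freedom between replicates, over genes with summed counts of at least 20, was 8.29. The labels give separate animal numbers for the replicates of a node group. For the joint replicates nothing says that they came from separate animals, so p-values there measure the spread between these samples, which may be partly technical. Each adjusted p covers the genes of 1 comparison. The 20 comparisons were not adjusted together.

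Counts were analysed with R 4.3.3 and edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10), which left 16149 joint and 18312 node genes, scaled by TMM, and tested with the quasi-likelihood F test in 1 fit per tissue over all its groups, which share an estimate of the spread. A gene passed at a Benjamini-Hochberg adjusted p below 0.05. Log2 fold changes are given with standard errors, each the absolute log2 fold change over the square root of its F statistic. Levels are given as CPM on the TMM scale with SDs, and library and list levels as log2 CPM with a prior count of 2. In joint soft tissue each RST day was compared with LST day 35, each RST day with the next, and all RST days together for any change. In nodes, Implant was compared with NoImplant and with ContraImplant, and ContraImplant with NoImplant, on each day, followed by day 14 with day 7 within Implant and NoImplant nodes and by the interactions of day with the Implant effects.

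The 35 gene lists, of 10 to 26 members each and written from textbook knowledge, were acute inflammatory cytokines and chemokines, neutrophil, monocyte and recruited macrophage, tissue-resident macrophage, osteoclast, osteoblast and bone matrix, chondrocyte and cartilage matrix, fibrillar matrix and activated fibroblasts, TGF-beta family, matrix proteases and inhibitors, synovial lining, mature skeletal muscle, muscle regeneration, adipocyte, endothelial, cell cycle, type I interferon response, interferon-gamma response, class II antigen presentation, T cell, T helper, cytotoxic and NK cell, B cell, germinal centre B cell, plasma cell, dendritic cell, lymph node stroma, lymph node macrophage, erythroid, mast cell, Schwann cell and nerve, skin epidermis, immediate early and dissection stress, mitochondrially encoded, and glycolysis and hypoxia. Some lists share members. Lists with at least 5 measured members were tested with limma 3.58.1's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with a correlation estimated per list. Members past the threshold were counted by the adjustment over all genes and by one over the list alone.

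Genes were named by a rule. In 6 comparisons (RST day 3 and day 35 against LST day 35, and Implant against NoImplant and against ContraImplant on each day) these were the 8 largest rises and 8 largest falls among genes past the threshold, with a mean raw count of at least 50 in the higher group and CPM ranges that did not overlap. In the others they were the 4 largest each way, and for the test of any change the 3 genes per day with the largest lead over the next highest day. Predicted and clone-named genes, pseudogenes and single antibody or T cell receptor segments were left out. Of a list, up to 4 members with the smallest adjusted p were named, and where no gene passed the 3 of smallest p. Not every gene the rule gives is used here. Groups, comparisons, lists, the naming rule and the settings to vary were fixed before the data were examined.

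For a gene with 0 counts over a group, the fold is a lower bound from a floor of 3 counts over the group. With 1 to 3 counts it is a ratio with a 95% counting interval. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. List medians with such genes at their bound moved at most for the lymph node macrophage list, from 2.14 to 2.03 on RST day 14, 1.73 to 1.6 on day 21 and 0.93 to 0.87 on day 35.

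The settings varied were the test, with DESeq2 1.42.0 in place of edgeR (Wald or likelihood ratio test), its size factors inside edgeR, no filter on low counts, a fit of the compared groups alone, the replicate number as a block, each of the 42 libraries left out in turn, and the estimated correlation. Settings added after the data were seen are named as such with their results. Implant and ContraImplant nodes with the same animal number came from the same mouse, so these numbers pair them. The correlation of their deviations from the group means was 0.35, 0.11 and 0.12 on day 7 and 0.4, 0.18 and 0.37 on day 14.

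Fit and calls were tested on counts simulated from the real means and library sizes with 200 genes changed. At 1.5-, 2- and 4-fold, 52.2, 79.1 and 95.5% of changed genes were recovered for RST against LST day 35 (15978 genes), 28.4, 59.7 and 89.4% for Implant against NoImplant day 14 (18143 genes) and 37.3, 58.2 and 87.9% for Implant against ContraImplant day 7 (18173 genes). Of unchanged genes 0.08, 0.04 and 0.01% were called. A simulated rise of the cell cycle list was recovered in each, with 0 of 33 other lists called. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 made summaries and plots. Raw reads were not used.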

Results

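RNA was sequenced from 2 tissues of C57BL/6 wild-type mice in a study of knee arthroplasty, an operation that replaces part of the joint with an implant. The stated aim was to follow the molecular pathways of repair after surgery and of the draining nodes. The joint soft tissue set held 24 libraries in 6 groups of 4, labelled RST day 3, 7, 14, 21 and 35 and LST day 35. The labels do not spell out RST and LST, so the codes are kept here, and LST was sampled on day 35 alone. A difference between RST on an earlier day and LST day 35 is therefore a difference of label and of day at once. The lymph node set held 18 libraries in 6 groups of 3, from Implant, ContraImplant and NoImplant nodes on days 7 and 14. Animal numbers in the labels place each ContraImplant node on the other side of the same mouse as the Implant node of that number, while NoImplant nodes came from other mice. The count columns name both ContraImplant and NoImplant nodes as without surgery, and Implant nodes as with surgery.

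Total counts per joint library were 17842090 to 23217719 on day 3, 20317132 to 25337254 on day 7, 20129243 to 27444537 on day 14, 20563850 to 24814864 on day 21, 21849869 to 24993500 for RST day 35 and 23275924 to 28024003 for LST day 35. In the nodes the totals on days 7 and 14 were 23578030 to 26506352 and 26693805 to 32930546 for NoImplant, 23709158 to 44371001 and 25147670 to 30654696 for ContraImplant, and 22041900 to 25178761 and 24057399 to 27997692 for Implant. In the joint samples, where muscle genes were abundant, the 20 most abundant genes took 33.44 ± 0.88% of counts in LST day 35 and 21.1 ± 1.8% in RST day 3 (SD, n = 4). Mitochondrially encoded genes took 10.48 ± 0.58% in LST day 35, 4.62 ± 0.84% in RST day 7 and 10.54 ± 0.67% in RST day 35. In the nodes that share ran from 1.31 to 4.08%, and segments of antibody and T cell receptor genes took 0.76 to 3.98%. The first principal component carried 65.2% of the variance in the joint and 30.9% in the nodes.

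**Figure D1:**
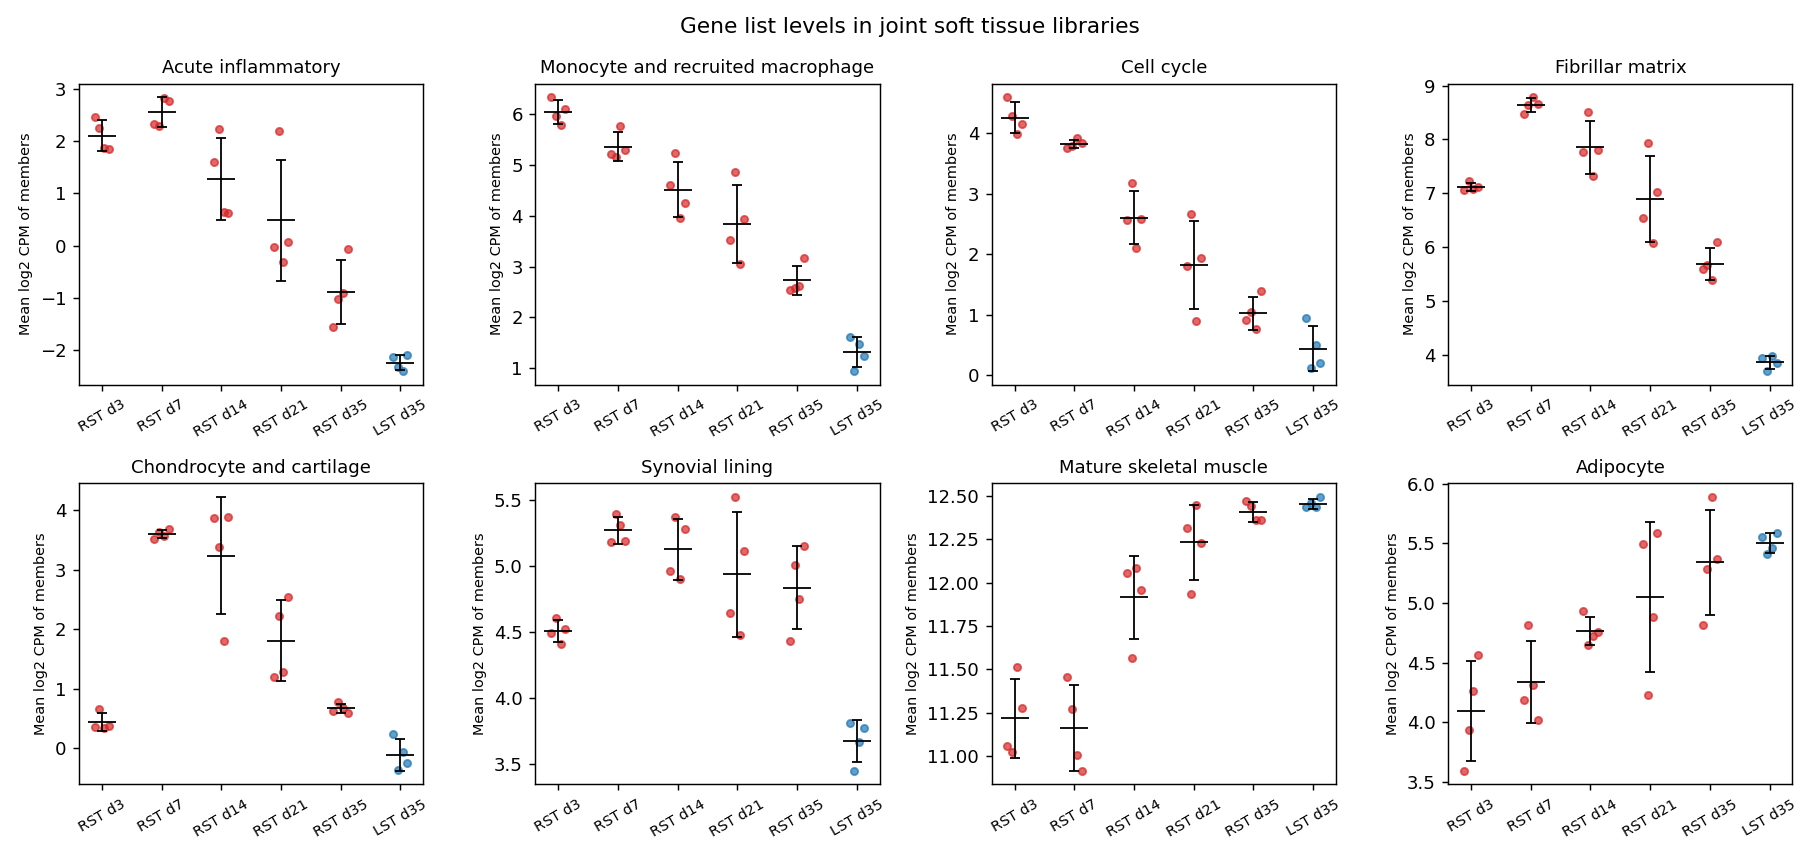
Level of 8 gene lists in the 24 joint soft tissue libraries, as the mean log2 CPM of each list's members (y axis) by group (x axis); points are libraries, the black bar is the group mean and the error bars are the SD (n = 4). The fibrillar matrix list stood at 8.64 ± 0.12 in RST day 7, 5.69 ± 0.30 in RST day 35 and 3.86 ± 0.12 in LST day 35.

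The first comparison asked which genes differed in joint soft tissue early after surgery, on RST day 3, from LST day 35. Genes of wound inflammation were far higher. Arg1, the arginase of macrophages in healing wounds (chromosome 10, 24915221 to 24927484, minus strand, mm10), stood at 60.4 ± 23.0 CPM on RST day 3 and at 0.0602 ± 0.0467 CPM in LST day 35 (SD, n = 4). Ccl2, which draws monocytes out of the blood, was at 27.1 ± 11.9 against 0.379 ± 0.159 CPM, and Trem2, a receptor of lipid-handling macrophages, at 55.2 ± 18.7 against 0.361 ± 0.0614 CPM. In the other direction Retnla, a marker of alternatively activated macrophages (chromosome 16, 48842551 to 48844461, plus strand), was at 0.972 ± 0.518 against 18.6 ± 4.53 CPM. Pvalb, the calcium buffer of fast muscle fibres, was at 2132 ± 364 against 10390 ± 1510 CPM.

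In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 11101 of 16149 genes passed, 6234 higher and 4867 lower on RST day 3. Of these, 4864 differed more than 2-fold, 3416 upward and 1448 downward. The log2 fold change was 9.89 ± 0.69 (SE) for Arg1 (edgeR adjusted p = 1.6e-10), 7.78 ± 0.96 for the neutrophil chemokine Cxcl5 (2.83e-07), −4.26 ± 0.41 for Retnla (7.39e-09) and −2.28 ± 0.20 for Pvalb (2.57e-09). Other large rises were those of Clec4d (7.34 ± 0.66), a receptor for microbial glycolipids on myeloid cells, and Chrng (7.41 ± 1.04), the fetal subunit of the muscle acetylcholine receptor. Falls beside Retnla were those of Prss55 (−3.76 ± 0.37), Ostn (−3.37 ± 0.42), Fgf6 (−3.3 ± 0.34) and Actc1 (−3.29 ± 0.35). Genes with 1 to 3 counts over the LST group are given as ratios of group means with 95% counting intervals: Orm2, an acute phase protein, 1650 (296 to 65300), the neuropeptide Gal 394 (70.4 to 15600), the receptor Clec4e 307 (84.8 to 2540) and the chemokine Cxcl3 248 (44.2 to 9840). Orm2 varied between the day 3 libraries, which held 26.2, 42.4, 4.53 and 1.09 CPM.

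By gene list, inflammation, matrix and proliferation rose together on RST day 3. All 17 measured members of the acute inflammatory list rose (median log2 fold change 5.61), among them Ccl2 (6.16 ± 0.39) and Ccl7 (6.51 ± 0.5). All 20 monocyte and recruited macrophage markers rose (median 4.47), with Trem2 at 7.24 ± 0.41 and the chemokine receptor Ccr2 at 4.46 ± 0.29. In the fibrillar matrix list 25 of 26 rose and none fell (median 3.27), with Cthrc1, a secreted protein of activated fibroblasts, at 6.64 ± 0.47 and periostin, Postn, at 5.85 ± 0.42. All 24 cell cycle genes rose (median 4.25), with the S phase cyclin Ccna2 at 4.63 ± 0.35. The type I interferon response list rose in all 21 members (median 2.55), with Oas1a at 4.13 ± 0.3. Of the mature muscle list 19 of 20 fell and none rose (median −1.25), of the adipocyte list 12 of 14 fell and 1 rose (−1.25), and all 8 mitochondrially encoded genes fell (−1.26). In the same libraries the muscle regeneration list had 10 of 15 members higher and 1 lower (median 1.08), with the fusion factor Mymk at 6.5 ± 0.58 and embryonic myosin, Myh3, at 3.69 ± 0.39.

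Among the other lists, rises and falls were 13 and 1 of 15 tissue-resident macrophage markers (median 2.33), 11 and 1 of 14 osteoclast markers (2.58), 13 and 2 of 17 TGF-beta genes (1.09), 17 and 1 of 19 matrix proteases and inhibitors (2.01), 11 and 0 of 11 class II presentation genes (1.73), 10 and 1 of 13 dendritic cell genes (2.11), 12 and 1 of 14 lymph node macrophage genes (3.24) and 12 and 2 of 19 interferon-gamma response genes (0.73; 13 rose adjusted over the list alone, and the list test was lost without RST day 3 replicate 4, camera adjusted p = 0.0796). The lists that did not pass the list test were neutrophil (10 rose and 0 fell of 17), osteoblast (3 and 5 of 14), cartilage (6 and 2 of 17, 5 and 2 over the list alone), synovial lining (6 and 4 of 14), endothelial (3 and 6 of 16), T cell (5 and 2 of 11), T helper (1 and 4 of 10), cytotoxic and NK cell (7 and 0 of 7), B cell (5 and 0 of 12), germinal centre B cell (6 and 2 of 10), plasma cell (8 and 2 of 16), lymph node stroma (4 and 2 of 13, 3 and 2 over the list alone), erythroid (0 and 1 of 11), mast cell (2 and 0 of 6), Schwann cell (1 and 7 of 12), immediate early (4 and 4 of 16, 2 and 4 over the list alone) and glycolysis (7 and 6 of 17). Skin epidermis had 4 measured genes, too few for a list test, of which 0 rose and 2 fell. Adjusted over the list alone the counts were equal to those over all genes tested except where a second count is given.

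With camera at a preset correlation, 17 of 34 lists passed, 14 upward and 3 downward. The cell cycle list had the smallest camera adjusted p (1.27e-15), followed by the monocyte (2.46e-13) and fibrillar matrix (1.91e-11) lists, and the adjusted p was 2.33e-08 for muscle. None of the 34 held with an estimated correlation, where the smallest adjusted p = 0.424. In 5 lists the median, the mean and the test differed in sign. The share of mitochondrial counts, 6.08 ± 0.46% on RST day 3 against 10.48 ± 0.58%, moved with the muscle list.

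On RST day 7 the cartilage and fibrillar matrix lists had their largest medians against LST day 35 among the 5 RST days. Tnn, an extracellular matrix glycoprotein (chromosome 1, 160085029 to 160153580, minus strand), was at 242 ± 16.3 against 0.610 ± 0.203 CPM (SD, n = 4), a log2 fold change of 8.61 ± 0.57 (edgeR adjusted p = 1.15e-10). Acan, the large proteoglycan of cartilage, was at 153 ± 28.6 against 0.444 ± 0.194 CPM (8.38 ± 0.53, edgeR adjusted p = 6.96e-11). Col1a1, the main fibrillar collagen chain, reached 11170 ± 1400 against 194 ± 9.28 CPM (5.85 ± 0.4), and Postn 2039 ± 143 against 11.7 ± 1.6 CPM. Acod1, which makes itaconate in activated macrophages, had 0 counts in LST day 35 and was at least 180-fold higher on RST day 7, while the granzyme Gzmd was at least 57.1-fold higher. The largest falls among named genes were those of Odf3l2 (−3.86 ± 0.61), Slc25a25 (−3.34 ± 0.8), Prima1 (−3.06 ± 0.33) and Arrdc2 (−3.03 ± 0.77). For genes with few LST counts the ratio was 455 (126 to 3770) for Clec4e and 286 (97.7 to 1390) for the osteoclast factor Tnfsf11.

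By edgeR 12287 genes passed on RST day 7, 6620 higher and 5667 lower. All 26 fibrillar matrix genes rose (median 4.93, camera adjusted p = 8.91e-18, and 0.419 with an estimated correlation), as did 14 of 17 cartilage genes with 2 lower (4.95, camera adjusted p = 0.000161, and 0.419 with an estimated correlation). Of the proteases and inhibitors 17 rose and 1 fell (3.88), with the macrophage elastase Mmp12 at 7.32 ± 0.53, and 12 of 14 osteoclast markers rose (3.33; 1 also fell over the list alone). Cell cycle (23 of 24 rose, 3.81), acute inflammatory (17 of 17, 5.59), monocyte (19 of 20, 4.11) and type I interferon genes (19 of 21, 1.91) were also higher. Mature muscle fell in 19 of 20 members (−1.35), the adipocyte list in 10 of 14 (−1.16) and the mitochondrial list in 8 of 8 (−1.73). Camera passed 18 of 34 lists, 15 upward and 3 downward, and 0 with an estimated correlation (smallest adjusted p = 0.419). The median, mean and test of 1 list differed in sign.

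On RST day 14 the cartilage and matrix genes were still high against LST day 35. Acan stood at 101 ± 42.9 CPM (log2 fold change 7.8 ± 0.53, edgeR adjusted p = 1.7e-09) and Mmp12 at 36.6 ± 11.4 CPM (7.67 ± 0.53; n = 4). Acod1 was at least 227-fold higher and the anti-inflammatory cytokine Il10 at least 4.17-fold higher, against 0 counts in LST. Clec4e had a ratio of 309 (85.4 to 2560), Tnfsf11 of 135 (46 to 658) and the muscle fusion factor Mymx of 27.2 (7.23 to 230). Falls were smaller, as in Cyp2e1 (−1.61 ± 0.66) and Prima1 (−1.54 ± 0.3). In all 9350 genes passed edgeR's test, 5387 higher and 3963 lower. The fibrillar list rose in 25 of 26 members (median 4.26, camera adjusted p = 9.28e-30, and 0.283 with an estimated correlation), cartilage in 15 of 17 with 1 lower (4.3), proteases in 16 of 19 (3.5), monocyte markers in 18 of 20 (3.38) and the cell cycle in 22 of 24 (2.67). Muscle fell in 10 of 20 (7 over the list alone; −0.46), the adipocyte list in 6 of 14 (4 over the list alone; −0.73) and the mitochondrial list in 8 of 8 (−0.7). Camera passed 21 lists, 18 upward and 3 downward, with 0 at an estimated correlation (smallest adjusted p = 0.283) and 2 lists differing in sign.

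On RST day 21 matrix and synovial lining genes were above LST day 35 while no gene of the mature muscle list passed. Il1rn, the interleukin-1 receptor antagonist (chromosome 2, 24336853 to 24351494, plus strand), had a log2 fold change of 6.71 ± 1.04 (edgeR adjusted p = 4.94e-05) and Cthrc1 of 6.11 ± 0.46 (7.46e-08). Prg4, the lubricin that coats joint surfaces, stood at 1092 ± 744 CPM against 53.3 ± 29.1 (n = 4). Acod1 was at least 175-fold and Il10 at least 3.2-fold higher. Ratios were 192 (52.9 to 1590) for Clec4e, 74.2 (25.1 to 363) for Tnfsf11, 27.7 (7.29 to 235) for Mymx and 9.59 (2.95 to 49.4) for granzyme B, Gzmb. Falls were those of Cish (−1.59 ± 0.5), the heat shock gene Hspa1a (−1.14 ± 0.33), G0s2 (−1.1 ± 0.25) and Slc1a1 (−1.07 ± 0.26). Fibrillar genes rose in 25 of 26 (median 3.27, camera adjusted p = 3.29e-43, and 0.109 with an estimated correlation), monocyte markers in 18 of 20 (2.58), cartilage in 11 of 17 (2.03; 13 adjusted over the list alone), synovial lining in 9 of 14 (1.14; 10 over the list alone) and B cell genes in 7 of 12 (1.54; 9 over the list alone). Muscle (−0.16), adipocyte (−0.35) and mitochondrial genes (−0.28) had 0 members past edgeR's threshold, though camera passed each list downward (adjusted p = 0.0136, 0.0273 and 0.0165, and 0.483, 0.429 and 0.429 with an estimated correlation). Camera passed 23 lists, 19 upward and 4 downward, 0 with an estimated correlation, and 3 lists differed in sign. By edgeR 4375 genes passed, 3499 higher and 876 lower, and by DESeq2 4950. Without RST day 21 replicate 2, whose acute inflammatory list stood at 2.20 against −0.31 to 0.06 in the others, edgeR called 2502, and the muscle and adipocyte lists no longer passed (camera adjusted p = 0.0599 and 0.16). The adipocyte list was also lost without RST day 21 replicate 3 (camera adjusted p = 0.0643).

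On day 35, where RST and LST were sampled at the same time, genes of lubrication, matrix turnover and macrophages were still higher in RST. Mmp12, the macrophage elastase (chromosome 9, 7344381 to 7369499, plus strand), was at 14.4 ± 7.1 CPM in RST and 0.176 ± 0.0334 in LST (SD, n = 4), a log2 fold change of 6.33 ± 0.55 (edgeR adjusted p = 1.22e-06). Prg4 (chromosome 1, 150449412 to 150466165, minus strand) stood at 1087 ± 679 against 53.3 ± 29.1 CPM (4.35 ± 0.55, edgeR adjusted p = 6.87e-05), and Has1, a hyaluronan synthase (chromosome 17, 17843323 to 17855205, minus strand), at 15.1 ± 9.68 against 0.623 ± 0.258 CPM (4.6 ± 0.71, edgeR adjusted p = 0.000487). Timp1, an inhibitor of matrix metalloproteases (chromosome X, 20870166 to 20874735, plus strand), was at 23.3 ± 11.5 against 1.25 ± 0.242 CPM (4.22 ± 0.49, edgeR adjusted p = 3.17e-05). Spp1, osteopontin, was at 90.4 ± 28 against 5.55 ± 1.16 CPM (4.03 ± 0.45).

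Of the 479 genes that passed edgeR's test on day 35, 471 were higher and 8 lower in RST, and 357 differed more than 2-fold, 350 upward and 7 downward. The rest of the 8 largest rises were those of Il1rn (4.81 ± 1.19; 2.75 ± 2.3 against 0.0911 ± 0.0314 CPM), the desmosome protein Pkp1 (4.77 ± 0.55; 3.98 ± 2.35 against 0.145 ± 0.133 CPM; chromosome 1, 135871395 to 135919207), the hyaluronan-degrading protein Cemip (4.43 ± 0.59) and Tmem196 (4.37 ± 0.59). Mss51, a regulator of muscle metabolism (chromosome 14, 20482867 to 20496901, minus strand), was the single fall that met the naming rule, at 39.7 ± 14.1 against 98.9 ± 38.1 CPM (−1.32 ± 0.33, edgeR adjusted p = 0.027). The dendritic cell chemokine Ccl22 had a ratio of 13.3 (4.21 to 67.3).

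**Figure D2:**
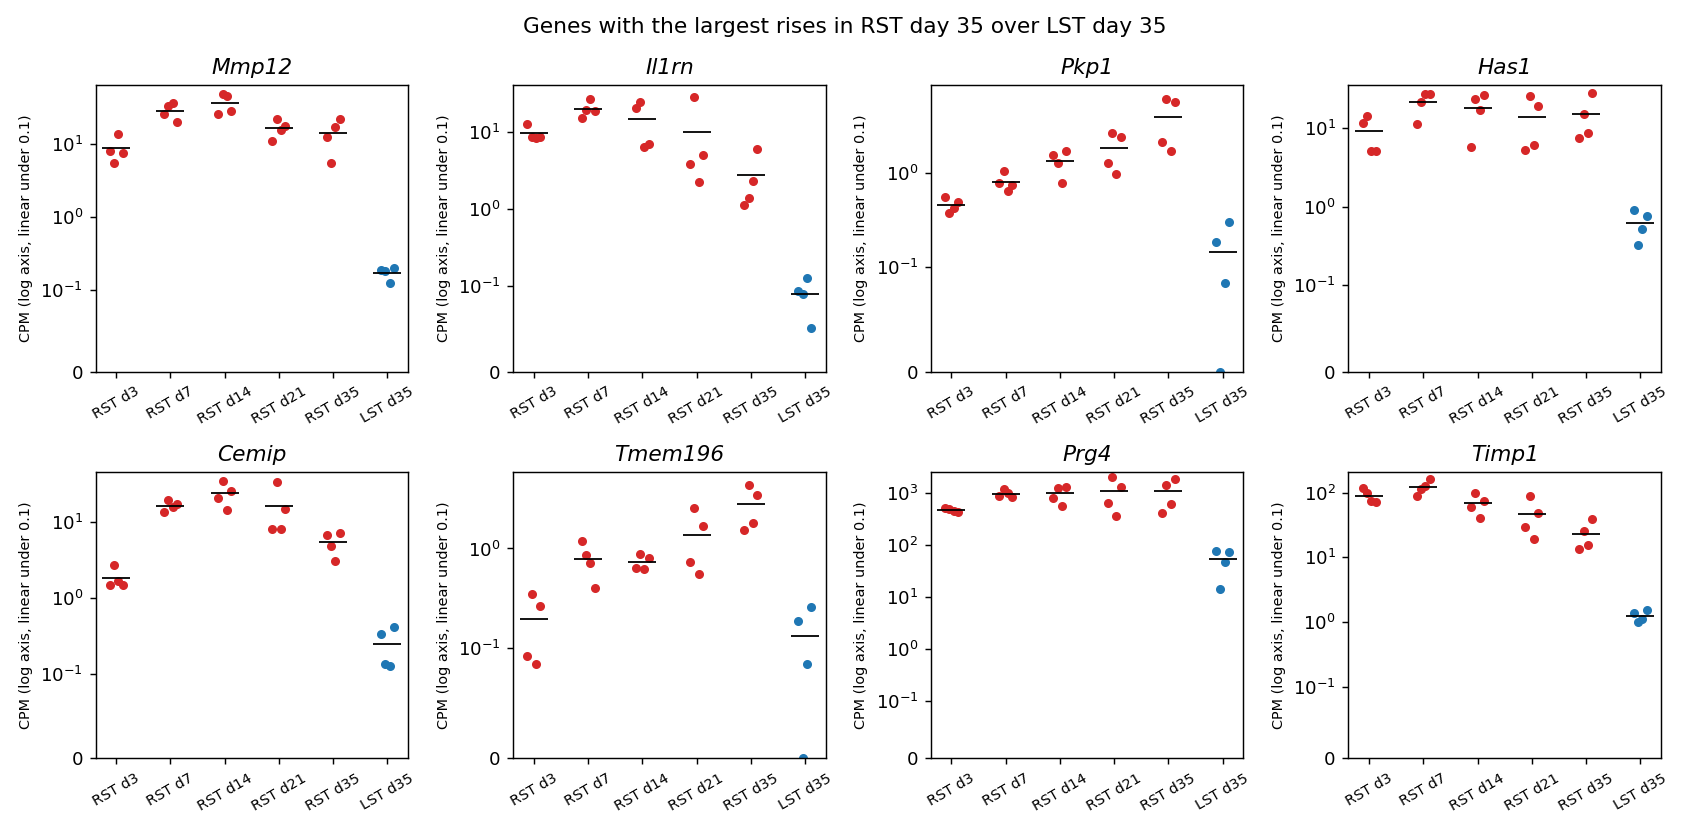
CPM (y axis, logarithmic, linear under 0.1) of the 8 genes with the largest rises in RST day 35 over LST day 35, by group (x axis); points are libraries and bars are group means (n = 4). Prg4 stood at 471 ± 38.4 CPM on RST day 3, 1087 ± 679 on RST day 35 and 53.3 ± 29.1 on LST day 35.

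The fibrillar matrix list led on day 35: 19 of 26 members rose and none fell (24 adjusted over the list alone; median log2 fold change 1.5), with Cthrc1 at 4.21 ± 0.47, Ltbp2 at 3.65 ± 0.39 and tenascin C, Tnc, at 3.24 ± 0.38. Of the proteases and inhibitors 10 rose (12 over the list alone; median 1.41), with stromelysin, Mmp3, at 3.86 ± 0.46 and cathepsin K at 2.78 ± 0.36. Monocyte and recruited macrophage markers rose in 9 of 20 (13 over the list alone; 1.43), with Trem2 at 3.84 ± 0.45 and fibronectin, Fn1, at 3.58 ± 0.45. Synovial lining genes rose in 5 of 14 (8 over the list alone; 0.54), with Prg4, Has1 and Htra1 (1.81 ± 0.26). These 4 lists held in camera with an estimated correlation, at adjusted p = 0.026, 0.026, 0.0452 and 0.026, after preset values of 3.03e-57, 4.68e-26, 4.47e-24 and 4.52e-11.

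Camera passed 18 of 34 lists on day 35, 16 upward and 2 downward. The 14 others that passed lost the call with an estimated correlation (adjusted p from 0.0926, for class II presentation, to 0.573, for the cell cycle). Among them tissue-resident macrophage markers had 6 members higher and 1 lower (11 and 1 over the list alone), class II presentation 5 higher (9 over the list alone) and osteoclast markers 3 (7 over the list alone). Other counts were 6 higher for TGF-beta (7 over the list alone), 1 for the acute inflammatory list (3) and 0 for the cell cycle. For cartilage it was 3 (4), with Acan at 3.57 ± 0.58. The Schwann list had a median of −0.68 and passed downward (camera adjusted p = 0.00142, and 0.4 with an estimated correlation), though its 1 member past edgeR's threshold, the node of Ranvier protein Gldn, rose (1.69 ± 0.43), and the list was lost without LST replicate 3 (camera adjusted p = 0.184). Mature muscle (median −0.06), adipocyte (−0.13), endothelial (−0.07), mitochondrial (−0.01) and type I interferon genes (0.18) had 0 members past the threshold, and limma camera adjusted p = 0.0595, 0.0956, 0.0595, 0.449 and 0.758. The median, mean and test of 3 lists differed in sign. The count rested on several libraries: edgeR called 182 genes without RST replicate 4, 318 without RST replicate 2, and 216, 291 and 266 without LST replicates 2, 3 and 4. It called 751 with no filter on low counts and 915 with these groups alone, and DESeq2 called 783.

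From RST day 3 to day 7 cartilage genes rose and type I interferon genes fell. Prss35, a secreted serine protease-like protein (chromosome 9, 86743649 to 86758443, plus strand), went from 0.598 ± 0.269 to 36.2 ± 6.16 CPM (SD, n = 4), a log2 fold change of 5.87 ± 0.57 (edgeR adjusted p = 1.09e-07). Acan went from 9.07 ± 1.25 to 153 ± 28.6 CPM (4.07 ± 0.38, edgeR adjusted p = 6.23e-08), and Col11a1 (4.56 ± 0.41) and Ucma (5.06 ± 0.56), both of cartilage, rose with it. Chil3, a chitinase-like protein of monocytes and macrophages, went from 29.6 ± 6.21 to 2.19 ± 1.76 CPM (−3.74 ± 0.62, edgeR adjusted p = 6.61e-05), and the iron-binding Lcn2 fell by 3.42 ± 0.52 on the log2 scale. Against few day 3 counts, Gzmd had a ratio of 66.5 (22.5 to 325) and the choline transporter Slc5a7 of 61 (20.6 to 298). Of 6648 genes that passed, 3013 rose and 3635 fell, and with these groups alone 3075 rose and 2818 fell. The cartilage list rose in 15 of 17 (median 3.98, camera adjusted p = 6.19e-15, and 0.106 with an estimated correlation), fibrillar matrix in 24 of 26 (1.59) and endothelial genes in 10 of 16 (0.39). The type I interferon list fell in 14 of 21 (16 over the list alone; −0.79), with Oas1a at −1.31 ± 0.24, and the cell cycle in 7 of 24 (5 over the list alone; −0.48, camera adjusted p = 0.045, and 0.899 with an estimated correlation). The cell cycle call was lost without RST day 3 replicate 1 or 2 (camera adjusted p = 0.151 and 0.0557) or day 7 replicate 1, 2 or 4 (0.0946, 0.0586 and 0.0548). Monocyte markers split, with 3 higher and 9 lower (3 and 11 over the list alone), and did not pass (limma camera adjusted p = 0.0758). Camera passed 14 lists, 10 upward and 4 downward, 0 with an estimated correlation (smallest adjusted p = 0.106), and 4 lists differed in sign.

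From RST day 7 to day 14 proliferation and embryonic muscle genes fell while mature muscle genes rose. Myh3 went from 106 ± 38.2 to 10.8 ± 5.32 CPM (−3.29 ± 0.36) and the perinatal myosin Myh8 fell too (−2.97 ± 0.3, edgeR adjusted p = 4.32e-06). Mki67, a marker of dividing cells, went from 44.1 ± 4.32 to 19.3 ± 9.36 CPM (SD, n = 4). Arg1 fell by 3.56 ± 0.44 and B3gat1 by 3.82 ± 0.39 on the log2 scale, and the gluconeogenic muscle enzyme Fbp2 rose by 2.26 ± 0.29. The cell cycle list fell in 23 of 24 (24 over the list alone; median −1.21, camera adjusted p = 6.37e-11, and 0.456 with an estimated correlation). Muscle regeneration had 1 higher and 8 lower of 15 (1 and 9 over the list alone; −1.32). Mature muscle rose in 16 of 20 (18 over the list alone; 0.77), with enolase 3, Eno3, at 1.23 ± 0.21, and mitochondrial genes in 7 of 8 (8 over the list alone; 0.98). Fibrillar matrix fell in 12 of 26 (17 over the list alone; −0.75). Of 6284 genes that passed, 3377 rose and 2907 fell. Camera passed 7 lists, 2 upward and 5 downward, 0 with an estimated correlation (smallest adjusted p = 0.456), and 2 differed in sign.

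From RST day 14 to day 21 Nrk (chromosome X, 138914430 to 139010532) went from 6.97 ± 3.53 to 1.64 ± 0.768 CPM (−2.1 ± 0.31, edgeR adjusted p = 0.00517), the imprinted gene Mest from 57.2 ± 28.2 to 14.2 ± 8.98 CPM (−1.99 ± 0.3) and Egfl6 from 8.68 ± 2.42 to 2.33 ± 0.909 CPM (−1.88 ± 0.29; n = 4). Acan (−1.66 ± 0.34), Matn3 (−2.04 ± 0.43) and Col11a1 (−1.75 ± 0.36) fell with 6 more of the 17 cartilage genes, 9 in all (15 over the list alone; camera adjusted p = 6.03e-11, and 0.315 with an estimated correlation). A small rise was that of the muscle atrophy ligase Trim63 (0.69 ± 0.16). Fibrillar matrix (median −0.8) and cell cycle (−0.75) had 0 members past the threshold over all genes and 18 and 16 lower over the list alone. Without day 21 replicate 2 their medians were −1.28 and −1.18, and that of the cell cycle was −0.47 without day 14 replicate 2. Camera passed 18 lists, 4 upward and 14 downward, 0 with an estimated correlation (smallest adjusted p = 0.315), and 1 differed in sign. In all 119 genes passed edgeR's test, 14 higher and 105 lower, and 4151 had an unadjusted p under 0.05. The count depended on single libraries: it was 4466 without day 21 replicate 2, 1322 without day 14 replicate 3, 2, 4 and 15 without day 21 replicates 1, 3 and 4, and 15, 4 and 66 without day 14 replicates 1, 2 and 4. DESeq2 called 1218, of which 582 rose and 636 fell, so the share of falls depended on the setting (1756 rose and 2710 fell without day 21 replicate 2, 378 and 944 without day 14 replicate 3). With these groups alone edgeR called 0.

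From RST day 21 to day 35 matrix and macrophage genes fell. Postn (chromosome 3, 54361109 to 54391037, plus strand) went from 301 ± 215 to 47.7 ± 11.7 CPM (SD, n = 4), a log2 fold change of −2.66 ± 0.36 (edgeR adjusted p = 0.00311). Acan went from 31.9 ± 24.9 to 5.42 ± 1.18 CPM (−2.57 ± 0.38), Prss35 from 2.91 ± 3.39 to 0.242 ± 0.226 (−3.58 ± 0.75), and Tnn (−2.61 ± 0.41), Cxcl5 (−2.84 ± 0.7) and Col1a1 (−2.02 ± 0.34) fell too. The lipolysis inhibitor G0s2 rose by 1.05 ± 0.25. Fibrillar matrix fell in 18 of 26 (23 over the list alone; median −1.4, camera adjusted p = 2.17e-24, and 0.371 with an estimated correlation), monocyte markers in 8 of 20 (17 over the list alone; −1.07), acute inflammatory genes in 5 of 17 (15 over the list alone; −1.91), the cell cycle in 5 of 24 (18 over the list alone; −1.09) and cartilage in 4 of 17 (10 over the list alone; −1.57). Without day 21 replicate 2, whose acute inflammatory level was 2.2 against −0.31 to 0.06 in the others, the medians of that list and of the cell cycle were −0.7 and −0.68. Synovial lining had 0 members past the threshold (3 lower over the list alone; median 0.02, limma camera adjusted p = 0.74). Camera passed 19 lists, 2 upward and 17 downward, 0 with an estimated correlation (smallest adjusted p = 0.371), and 4 differed in sign. Of 641 genes that passed edgeR's test, 13 rose and 628 fell. The count was 35 without day 21 replicate 2, 1350, 1884 and 191 without day 21 replicates 1, 3 and 4, and 67, 52 and 41 without day 35 replicates 1, 2 and 3. With these groups alone edgeR called 0, and DESeq2 called 1216.

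Across RST days 3 to 35 edgeR's test of any change passed 12852 genes. Of these 28.9% had their highest mean on day 3, 27.5% on day 7, 5.9% on day 14, 4.2% on day 21 and 33.6% on day 35. The genes with the largest lead over the next highest day were Orm2 (log2 lead 5.02), Chil3 (3.76) and Lcn2 (3.44) on day 3, Gzmd (3.62), Cdh3 (3.41) and Gzme (3.26) on day 7, and Col10a1, the collagen of hypertrophic cartilage (2.14), Kera (0.97) and Ptx4 (0.96) on day 14. On day 21 they were the retinoic acid hydroxylase Cyp26b1 (1.51), the antibody light chain constant gene Igkc (0.48) and Pfkfb3 (0.42), and on day 35 Pkp1 (1.1), Bdh1 (1.02) and Kcnf1 (1.01).

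**Figure D3:**
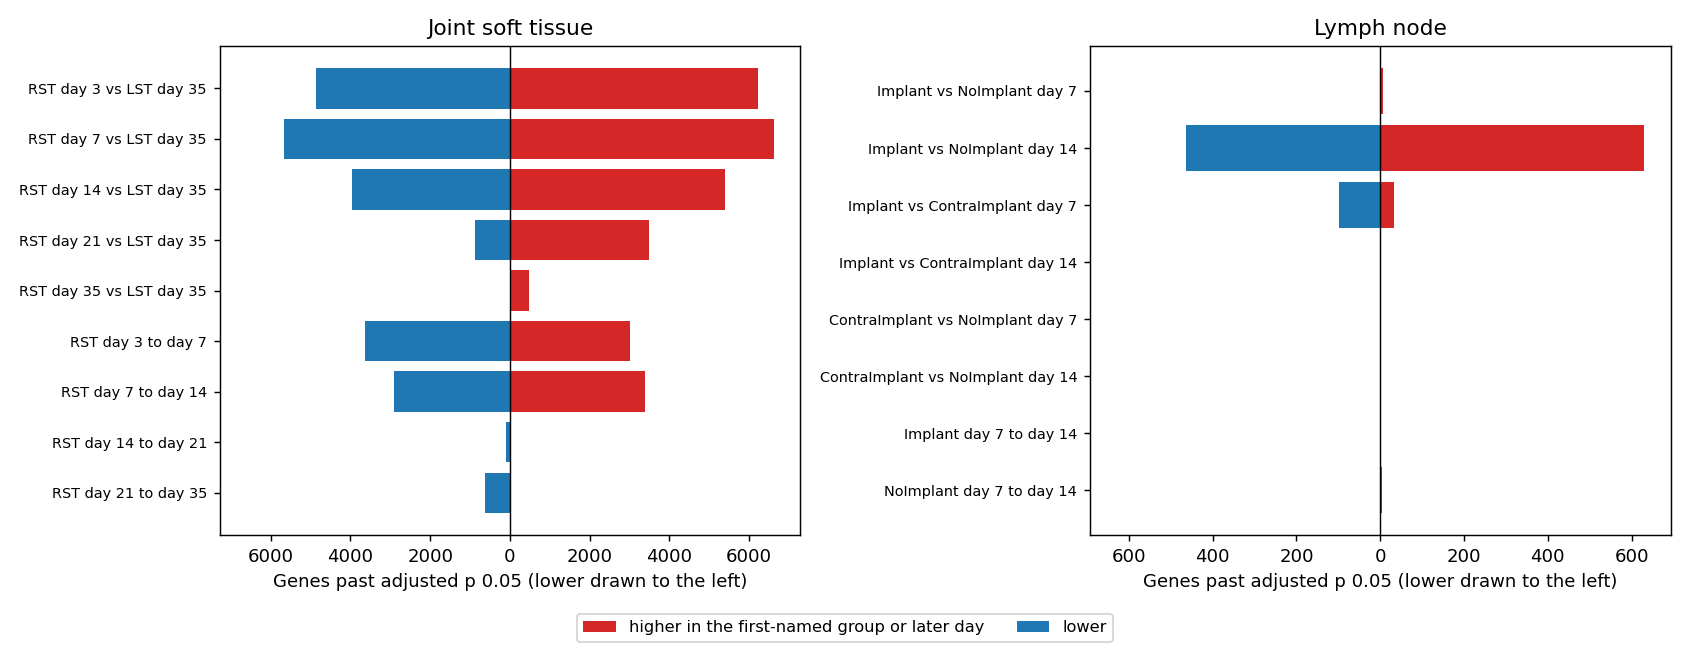
Number of genes past an adjusted p of 0.05 in edgeR's test (x axis) for each comparison (y axis), higher in the first-named group or on the later day to the right in red and lower to the left in blue, for joint soft tissue and lymph node separately. On day 35 RST had 471 genes higher and 8 lower than LST, and Implant nodes on day 14 had 630 higher and 464 lower than NoImplant nodes.

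In the lymph nodes, the first question was how Implant nodes differed from NoImplant nodes on day 7. Icos, a costimulatory receptor of follicular helper and regulatory T cells (chromosome 1, 60977927 to 61000320, plus strand), stood at 66.9 ± 3.87 CPM in Implant and 42.7 ± 2.03 in NoImplant nodes (SD, n = 3), a log2 fold change of 0.65 ± 0.11 (edgeR adjusted p = 0.0429). Ikzf2, the transcription factor Helios of regulatory T cells, was at 72.5 ± 2.13 against 52.7 ± 2.46 CPM (0.46 ± 0.06, edgeR adjusted p = 0.0108). Cdk2, a kinase of the entry into S phase, was at 79.7 ± 1.43 against 56.3 ± 0.979 CPM (0.5 ± 0.08, edgeR adjusted p = 0.0321). Fjx1 (chromosome 2, 102449366 to 102452499, minus strand) was at 8.41 ± 0.458 against 2.92 ± 0.607 CPM (1.53 ± 0.22), and Bpifb3 at 0.368 ± 0.114 against 5.3 ± 2.89 CPM (−3.84 ± 0.56, edgeR adjusted p = 0.0205).

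These were 5 of 8 genes that passed, 7 higher and 1 lower, the rest being Dnph1 (1.11 ± 0.18), Slc9a5 (1.02 ± 0.14) and Rbpjl (1.82 ± 0.23), the last outside the naming rule and chosen after its values were seen. At an unadjusted p under 0.05 there were 3326 genes, and DESeq2 called 734. The cell cycle list had 0 of 24 members past the threshold over all genes and 24 higher adjusted over the list alone (median 1.11, camera adjusted p = 6.24e-19, and 0.596 with an estimated correlation), with Mki67 at 131 ± 18.6 against 57.6 ± 19.4 CPM. Tissue-resident macrophage markers had 0 past over all genes and 6 lower over the list alone (−0.58, camera adjusted p = 2.54e-06, and 0.596 with an estimated correlation). Fibrillar matrix had 0 and 6 higher (0.41), and the T helper list 2 and 5 higher (0.11). The type I interferon list (−1.12, camera adjusted p = 0.000133, and 0.686 with an estimated correlation) had 0 by either count, and turned to a median of 0.25 (camera adjusted p = 0.0923) without NoImplant replicate 3, where the list stood at 6.84 against 4.39 and 4.48 in the other NoImplant day 7 libraries. Markers of mature muscle (median −2.94) moved too, at 0.41 to 5.99 in NoImplant and 0.26 to 2.64 in Implant libraries, as did adipocyte genes (−1.37). Without NoImplant replicate 2 the muscle, adipocyte and T helper lists no longer passed (camera adjusted p = 0.156, 0.287 and 0.102), nor did the adipocyte list without Implant replicate 1 (camera adjusted p = 0.144). Camera passed 14 lists, 4 upward and 10 downward, 0 with an estimated correlation (smallest adjusted p = 0.596), and 4 differed in sign. The count of genes was 4 without NoImplant replicate 3 and 0 without any other of the 6 libraries, 55 with no filter (26 higher and 29 lower) and 1105 with these groups alone.

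On day 14 some matrix and B cell genes rose and some macrophage and vessel genes fell in Implant against NoImplant nodes. Col1a1 stood at 428 ± 96.8 against 199 ± 15.4 CPM (SD, n = 3), a log2 fold change of 1.1 ± 0.23 (edgeR adjusted p = 0.0245), and Col3a1 rose by 1.22 ± 0.23 (edgeR adjusted p = 0.0242). Ccn5, a matricellular protein (chromosome 2, 163820861 to 163833146, plus strand), was at 3.0 ± 1.28 against 0.478 ± 0.432 CPM (2.66 ± 0.62), and Mfap4, of elastic fibres, at 3.12 ± 0.664 against 0.768 ± 0.165 CPM (2.01 ± 0.43). C1qa, a complement component made by macrophages, was at 242 ± 44.2 against 442 ± 45.1 CPM (−0.87 ± 0.16, edgeR adjusted p = 0.0242). The antibody receptor Fcgr4 (chromosome 1, 171018920 to 171029761, plus strand) was at 1.68 ± 0.115 against 14.9 ± 9.7 CPM (−3.14 ± 0.59).

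By edgeR 1094 genes passed, 630 higher and 464 lower, of which 189 differed more than 2-fold, 45 upward and 144 downward. Other rises were those of Col28a1 (1.66 ± 0.45), Sfrp2 (1.51 ± 0.35), Col22a1 (1.48 ± 0.36), Scube1 (1.46 ± 0.35), Madcam1, the address molecule of high endothelial venules (1.35 ± 0.36), and Olfr164 (1.34 ± 0.34). Falls were those of Cd300e (−3.59 ± 0.8), of monocytes, Tyr (−3.16 ± 0.74), Bpifb2 (−2.67 ± 0.68), P2rx2 (−2.65 ± 0.58), Bpifb3 (−2.6 ± 0.5), Gbp2b (−2.56 ± 0.58) and Inmt (−2.3 ± 0.51). B cell genes rose in 6 of 16 (14 over the list alone; median 0.56, limma camera adjusted p = 4.65e-11) and fibrillar matrix in 5 of 25 (6 over the list alone; 0.38), while tissue-resident macrophage markers fell in 6 of 15 (9 over the list alone; −0.82), endothelial genes in 4 (7 over the list alone; −0.76), with the tight junction gene Cldn5 at −1.35 ± 0.23, and mast cell genes in 2 (9 over the list alone; −1.08). Each of these 5 had an adjusted p = 0.523 or more with an estimated correlation. The cell cycle (−0.06, limma camera adjusted p = 0.915) and type I interferon lists (0.18, 0.702) did not pass. Camera passed 13 lists, 3 upward and 10 downward, 0 with an estimated correlation (smallest adjusted p = 0.523), and 3 differed in sign.

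Adipocyte and dissection stress markers moved with this comparison. The adipocyte list stood at 3.41 to 4.94 in the Implant and 5.66 to 8.14 in the NoImplant libraries on day 14 (median fold change −3.28, camera adjusted p = 1.42e-06, and 0.523 with an estimated correlation), with 0 members past the threshold over all genes and 14 lower over the list alone. Adipoq, the hormone adiponectin of fat cells, was at 15.8 ± 14.3 against 194 ± 139 CPM (SD, n = 3). The immediate early and dissection stress list stood at 4.47 ± 0.06 against 4.79 ± 0.1 (median fold change −0.25, camera adjusted p = 0.026, 0.523 with an estimated correlation, and 0.111 without Implant replicate 1). Its members Dusp1 (−0.61 ± 0.13) and Jun (−0.72 ± 0.16) fell (6 fell and 1 rose over the list alone). With each library's adipocyte level as a covariate, a fit chosen after the data were seen, edgeR called 0 of the 1094 genes. The count was 372, 0 and 11 without Implant replicates 1, 2 and 3, and 0 and 4 without NoImplant replicates 2 and 3, and 620 with these groups alone, of which 263 were higher and 357 lower, so the balance turned. With no filter 364 were higher and 367 lower. DESeq2 called 2437, 1231 higher and 1206 lower.

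**Figure D4:**
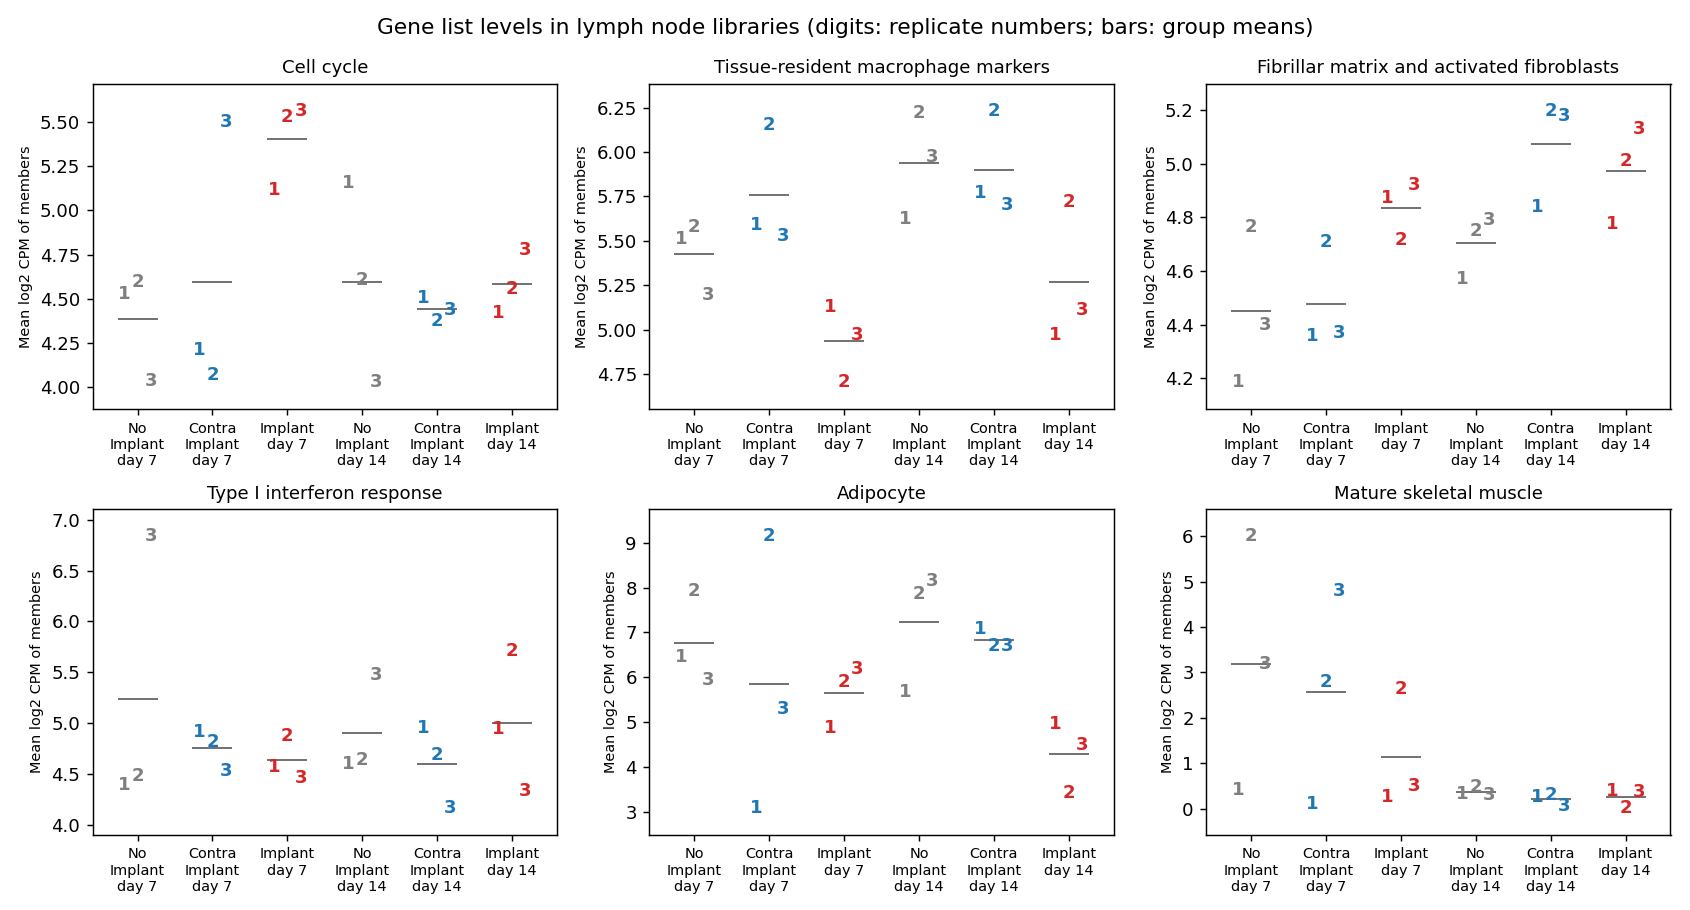
Level of 6 gene lists in the 18 lymph node libraries, as the mean log2 CPM of each list's members (y axis) by group and day (x axis); digits are replicate numbers at each library's value and bars are group means (n = 3). The tissue-resident macrophage list stood at 4.94 ± 0.21 in Implant and 5.76 ± 0.34 in ContraImplant nodes on day 7 (mean ± SD), and the adipocyte list of single libraries ran from 3.09 to 9.14.

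Implant nodes were next compared with ContraImplant nodes of the same mice on day 7. Col1a1 (chromosome 11, 94936224 to 94953042, plus strand) was at 388 ± 22.6 against 147 ± 43.1 CPM (SD, n = 3), a log2 fold change of 1.4 ± 0.23 (edgeR adjusted p = 0.0291), Mfap4 (chromosome 11, 61485431 to 61488900, plus strand) at 2.44 ± 0.519 against 0.395 ± 0.326 CPM (2.49 ± 0.46, edgeR adjusted p = 0.0319) and Fjx1 at 8.41 ± 0.458 against 2.73 ± 0.668 CPM (1.61 ± 0.22). Cd209d, a lectin of macrophages (chromosome 8, 3871824 to 3878555, minus strand), was at 5.48 ± 1.14 against 42.4 ± 20.4 CPM (−2.95 ± 0.48, edgeR adjusted p = 0.0291) and the folate receptor Folr2 (chromosome 7, 101839988 to 101857194, minus strand) at 4.07 ± 0.919 against 15.5 ± 6.0 CPM (−1.93 ± 0.31, edgeR adjusted p = 0.0291). With the animal as a block Col1a1 and Cd209d passed (edgeR adjusted p = 0.0232 and 0.0216). Mfap4, Fjx1 and Folr2 did not (0.0554, 0.0555 and 0.0555), at folds of 2.63, 1.62 and −1.89.

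Of 131 genes that passed, 32 were higher and 99 lower, and 63 differed more than 2-fold, 8 upward and 55 downward. Further rises were those of Tnn (1.56 ± 0.33), Col14a1 (1.25 ± 0.23), Col3a1 (1.15 ± 0.23) and Col1a2 (0.98 ± 0.16), and falls those of Bpifb3 (−3.58 ± 0.56), Bpifb2 (−3.41 ± 0.7), Gbp2b (−3.36 ± 0.61), Cd209e (−2.84 ± 0.56), Ptgds (−2.07 ± 0.36) and C1ql2 (−1.99 ± 0.41). Tissue-resident macrophage markers fell in 7 of 15 (11 over the list alone; median −0.89, camera adjusted p = 8.82e-13, and 0.306 with an estimated correlation), with C1qb at −0.92 ± 0.17, Timd4 at −1.15 ± 0.21 and Lyve1 at −1.0 ± 0.19. The lymph node macrophage list, which shares members with it, fell in 4 of 14 (7 over the list alone; −0.69), endothelial genes in 1 (14 over the list alone; −0.77), and fibrillar matrix rose in 4 of 25 (8 over the list alone; 0.29). The cell cycle list passed upward (0.71, camera adjusted p = 6.64e-11, and 0.498 with an estimated correlation) with 0 members past the threshold by either count. Mature muscle (−2.43) and mitochondrial genes (−0.76) passed downward (adjusted p = 0.7 and 0.638 with an estimated correlation). The latter turned to a median of 0.02 without ContraImplant replicate 2, whose mitochondrial share was 4.08%. Without Implant replicate 1 the mitochondrial list was lost too (camera adjusted p = 0.0998). The muscle list was lost without ContraImplant replicate 3 or Implant replicate 1 or 3 (camera adjusted p = 0.762, 0.0612 and 0.0637). The adipocyte list had a median of −1.91 and did not pass (limma camera adjusted p = 0.159). It stood at 3.09, 9.14 and 5.3 in the 3 ContraImplant libraries. Camera passed 15 lists, 4 upward and 11 downward, 0 with an estimated correlation (smallest adjusted p = 0.306), and 6 differed in sign.

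With the animal as a block, since both nodes came from the same mouse, edgeR called 19 genes on day 7, 5 higher and 14 lower, 14 of them among the 131. Of the further genes named above, Col3a1, Col1a2, Bpifb3 and Timd4 passed with the block (edgeR adjusted p from 0.0158 to 0.0402). Tnn, Col14a1, Bpifb2, Gbp2b, Cd209e, Ptgds, C1ql2, C1qb and Lyve1 did not (0.0554 to 0.0768), at folds of 1.58, 1.3, −3.28, −3.04, −2.72, −2.0, −1.97, −0.93 and −1.02. Without ContraImplant replicates 1, 2 and 3 the unblocked count was 2030, 0 and 600, and it was 0 without any of the 3 Implant libraries. It was 231 with no filter on low counts, 0 with these groups alone, and 1196 with the adipocyte covariate, and DESeq2 called 1113.

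On day 14 no gene passed edgeR's test between Implant and ContraImplant nodes: 1550 had an unadjusted p under 0.05 and DESeq2 called 11. The smallest p values were those of Alox5, which starts leukotriene synthesis, at 5.37 ± 1.1 against 11.9 ± 3.18 CPM (SD, n = 3; log2 fold change −1.15 ± 0.18, edgeR adjusted p = 0.255), Tppp3 (−0.88 ± 0.17) and Pigv (0.28 ± 0.05). Tissue-resident macrophage markers had 0 members past over all genes and 8 lower over the list alone (median −0.59, camera adjusted p = 5.66e-13, and 0.422 with an estimated correlation), and lymph node macrophage genes 0 and 4 (−0.36, camera adjusted p = 4.45e-07, and 0.456 with an estimated correlation). The adipocyte list had a median of −2.5 (camera adjusted p = 1.79e-11, and 0.61 with an estimated correlation). Camera passed 8 lists, 2 upward and 6 downward, 0 with an estimated correlation (smallest adjusted p = 0.422), and 5 differed in sign. With these groups alone edgeR called 136 genes, and 1 without ContraImplant replicate 3.

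ContraImplant and NoImplant nodes had no gene past edgeR's threshold on either day. On day 7 there were 1349 genes at an unadjusted p under 0.05 and 0 by DESeq2, with Sema7a (0.31 ± 0.06), the costimulatory ligand Cd86 (0.41 ± 0.09) and Rnf149 (0.37 ± 0.08) at the smallest p (edgeR adjusted p = 0.646). On day 14 there were 1062, and 23 by DESeq2, with Rbpjl (1.32 ± 0.23), Gapt (0.57 ± 0.1) and Rn7sk (−1.04 ± 0.21) at the smallest p (edgeR adjusted p from 0.49). The T cell list had a median of −0.23 on day 7 (limma camera adjusted p = 3.99e-09, and 0.594 with an estimated correlation). Neutrophil genes had one of 0.74, with 0 members past and 2 higher over the list alone (camera adjusted p = 5.45e-05, and 0.594 with an estimated correlation), lost without ContraImplant replicate 1 (camera adjusted p = 0.129). On day 14 fibrillar matrix had 0 and 5 higher (0.44, camera adjusted p = 2.91e-13, and 0.221 with an estimated correlation), the B cell list a median of 0.35 (4.64e-14, and 0.353) and the plasma cell list of −0.64 (2.08e-09, and 0.377). Camera passed 16 lists on day 7, 11 upward and 5 downward, and 14 on day 14, 4 upward and 10 downward, with 5 differing in sign on each day. None held with an estimated correlation, where the smallest adjusted p = 0.594 and 0.221.

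Between days 7 and 14 no gene passed in Implant nodes, where 1566 had an unadjusted p under 0.05 and DESeq2 called 53. Nptx2 (1.34 ± 0.22), Rgs2 (0.46 ± 0.08) and Ikzf2 (−0.35 ± 0.06) had the smallest p (edgeR adjusted p = 0.189). The cell cycle list there had 0 members past over all genes and 14 lower over the list alone (median −0.92, camera adjusted p = 9.46e-23, and 0.337 with an estimated correlation), and tissue-resident macrophage markers 0 and 6 higher (0.51, camera adjusted p = 2.82e-07, and 0.337 with an estimated correlation). With these groups alone edgeR called 178 genes, and 74 with the adipocyte covariate. In NoImplant nodes 3 genes rose: Prcp, a prolyl carboxypeptidase (chromosome 7, 92874470 to 92934583, plus strand), from 107 ± 3.64 to 140 ± 8.73 CPM (SD, n = 3; 0.39 ± 0.06, edgeR adjusted p = 0.0333), and Gm23935 (2.25 ± 0.29) and CT010467.1 (1.85 ± 0.22), which lay outside the naming rule and were chosen after their values were seen. DESeq2 called 791. The edgeR count was 327 and 7 without NoImplant day 14 replicates 1 and 3, 0 and 5 without day 7 replicates 2 and 3, 23 with no filter and 0 with these groups alone. Mast cell genes had 0 past over all genes and 8 higher over the list alone (1.3, camera adjusted p = 6e-10, and 0.274 with an estimated correlation), and mature muscle 0 and 18 lower (−5.17, camera adjusted p = 6e-10, and 0.327 with an estimated correlation). Camera passed 17 lists in Implant and 17 in NoImplant nodes, each 13 upward and 4 downward, 0 with an estimated correlation (smallest adjusted p = 0.262 and 0.274), with 6 and 2 differing in sign.

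The difference between days in the Implant effect was tested itself, as an interaction. Against NoImplant nodes 0 genes passed edgeR's test, 921 had an unadjusted p under 0.05 and DESeq2 called 5, with Gapt (0.9 ± 0.15), Il13ra2 (−0.87 ± 0.18) and Kmo (0.59 ± 0.13) at the smallest p (edgeR adjusted p = 0.278 for Gapt). Against ContraImplant nodes 0 passed, 334 had an unadjusted p under 0.05 and DESeq2 called 0, with Thbs3 (−1.14 ± 0.25), Fjx1 (−1.38 ± 0.31) and Ssc5d (−0.99 ± 0.24) at the smallest p. The cell cycle list was lower on day 14 than on day 7 in both interactions (median −1.18 with a camera adjusted p = 1.34e-21, and −0.54 with 7.64e-14), and these calls were lost with an estimated correlation (adjusted p = 0.613 and 0.649). Camera passed 9 and 15 lists, with 3 and 9 differing in sign.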

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

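All tests of regrouped libraries and the tests on RST day 21 replicate 2 and on RST day 3 against LST day 35 were chosen only after the results were seen. The tests on Implant against NoImplant nodes on day 14 were written before their own values were seen, but after the adipocyte levels of the libraries and the loss of the 1094 calls with the adipocyte covariate were known.

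One library stood apart in 9 of 228 groups of 4 tested for a gap to the nearest other library above Dixon's 95% critical share of the group's range, against 11.4 by chance (1 in 20). The mean log2 CPM was 2.20 for acute inflammatory genes in RST day 21 replicate 2 (others −0.31 to 0.06), 3.16 for monocyte markers (2.54 to 2.62) and 11.87 for mitochondrial genes (12.14 to 12.19) in RST day 35 replicate 4, 1.45 for B cell genes in RST day 35 replicate 2 (−0.64 to −0.37) and 2.17 for lymph node stroma in RST day 35 replicate 1 (2.39 to 2.43). In RST day 3 replicate 2 it was 0.67 for cartilage (0.34 to 0.38) and −0.05 for B cell genes (−0.44 to −0.38), in RST day 7 replicate 3 it was 3.91 for class II presentation (3.46 to 3.52), and in LST day 35 replicate 2 it was 0.67 for lymph node macrophage genes (1.05 to 1.12). The B cell list on RST day 35 no longer passed camera without replicate 2.

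RST day 21 replicate 2 lay toward the day 14 libraries: on the first principal component it was at −28.9, against 12.5 to 45.3 for the other day 21 libraries and −58.5 to 2.4 for day 14. Less muscle in the tissue piece would raise other tissues' lists alike. Against the other day 21 libraries its adipocyte genes differed by −1.09 ± 0.15 and fibrillar matrix genes by 1.40 ± 0.08 (SE over members, not libraries). This argues against it. An exchange with a day 14 library would need a partner nearer to day 21: the nearest, day 14 replicate 3, had a distance ratio of 0.986 (0.901 to 1.13), which leaves this undecided. A single library of another day under this label stays open: its mean distance to day 14 was 0.673 (0.618 to 0.725) of that to the others, which restates its place and tests nothing. A slower course of repair in that tissue stays open too, untested.

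In day 14 nodes the genes called between Implant and NoImplant may partly follow fat left on the nodes, as the adipocyte lists differed by −2.94. In the 12 other libraries 87.8% of called genes moved with the adipocyte list as needed, against 67.8% of genes not called. Leaving out a library gave 71.2 to 88.6%, so the excess may rest on a single one. The adipocyte level gave a median share of 0.252 (0.201 to 0.271) of the called fold changes. Picking called genes can lower this share, so it decides nothing. Thinning libraries to the smallest total left 1011 called, which argues against library size. With the adipocyte covariate the median fold change in the called direction went from 0.50 to 0.36 at a median SE of 0.12 and 0.13, all 1094 kept their sign and 999 had an unadjusted p under 0.05, so the calls ended because folds shrank at about the same error. An effect of the implant or of the operation, which differ together here, stays open beside fat, and with the covariate edgeR gave 0 calls.

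For RST day 3 against LST day 35, less muscle RNA would raise all other cell types alike. The medians of the monocyte and adipocyte lists differed by 5.72 (4.76 to 6.69 over members), which argues against it as the whole cause. A difference between lists does not depend on scaling, so the 5.72 argues against scaling as the whole cause too. DESeq2's size factors ended or turned 2.9% of the 11101 calls, but they moved the median gene by only −0.044, too little to test it. Label and day differ together here: the label at day 35 gave 479 genes and the RST days 12852, and their parts in the day 3 difference stay open.

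Groupings of the same libraries were counted, the real included. Each RST day against LST day 35, day 3 to 7 and day 7 to 14 had 35 splits of 4 against 4. Only the real split reached its count, so chance is unlikely if replicates are separate animals, which is unknown. The real and highest other counts were 11101 and 1 for day 3, 12287 and 0 for day 7, 9350 and 1929 for day 14, 4375 and 1991 for day 21, 479 and 18 for day 35, 6648 and 202 for day 3 to 7 and 6284 and 4871 for day 7 to 14. Of 60 splits drawn for any change 1 called as many (12852, highest other 5929). For day 14 to 21, 4 of 35 splits called at least the real 119, so chance is not excluded. The highest, 5533, exchanged day 14 replicate 3 with day 21 replicate 2 and points to a structure of these samples. For day 21 to 35, 2 of 35 called at least the real 641, so chance is not excluded. The highest, 1265, exchanged day 21 replicate 3 with day 35 replicate 4 and also points to such a structure.

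In the nodes 3 against 3 gives 10 splits, too few for a share under 0.05. Splits with at least the real count were 1 for Implant against NoImplant on day 7 (real 8, highest other 0) and day 14 (1094 and 0), 1 for Implant against ContraImplant on day 7 (131 and 15) and 1 for NoImplant day 7 to 14 (3 and 0). Among the 4 splits that part every animal's nodes as the real one does, the highest other count on day 7 was 0, and the 15 came from splits that keep a pair together. They were 10 for Implant against ContraImplant on day 14 (0 and 274, with ContraImplant replicate 3 exchanged with Implant replicate 1, which points to a structure of these samples), for ContraImplant against NoImplant on day 7 (0 and 2) and day 14 (0 and 0) and for Implant day 7 to 14 (0 and 0). For each interaction the real and all of the 20 splits drawn gave 0, too few for such a share.

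The effect of the Implant label differed between days 7 and 14 in camera tests of the interaction at the preset correlation, and in none with an estimated one. Against NoImplant nodes the median log2 difference was 2.97 for mature muscle (limma camera adjusted p = 5.27e-07), −1.62 for adipocyte (6.06e-05), −1.18 for cell cycle (1.34e-21), 1.16 for type I interferon (1.26e-06), 0.19 for class II (0.0113), −0.33 for T helper (0.000109), 0.32 for B cell (1.77e-09), −0.74 for plasma cell (9.35e-09) and −0.73 for mast cell genes (0.000578). With an estimated correlation the adjusted p = 0.613, or 0.673 for class II. The call ended without NoImplant day 7 replicate 2 for muscle (median 0.56), without NoImplant day 7 replicate 3 for type I interferon (−0.03), without Implant day 7 replicate 3 for mast cells (−0.42), and for class II without Implant day 14 replicate 2, Implant day 7 replicate 1, NoImplant day 14 replicate 2 or NoImplant day 7 replicate 1 (0.15, 0.13, 0.12 and 0.18).

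Against ContraImplant nodes it was 0.24 for monocyte (limma camera adjusted p = 0.0362), 0.27 for tissue-resident macrophage (0.021), −0.34 for fibrillar matrix (2.84e-14), 2.45 for muscle (2.53e-05), −0.38 for adipocyte (1.05e-05), 0.39 for endothelial (0.000707), −0.54 for cell cycle (7.64e-14), 0.51 for type I interferon (0.00325), 0.23 for interferon-gamma (0.0025), −0.10 for class II (0.0362), 0.28 for cytotoxic (0.000404), 0.58 for germinal centre B cell (0.00441), 0.30 for dendritic (0.00441), 0.20 for lymph node macrophage (0.0276) and 0.51 for mast cell genes (0.00441). With an estimated correlation the adjusted p = 0.235 for fibrillar matrix and 0.649 to 0.721 for the others. All but fibrillar matrix and cell cycle lost the call without at least 1 library (medians without it given). Without ContraImplant day 14 replicate 3 these were monocyte (0.20), tissue-resident macrophage (0.15), type I interferon (0.35), interferon-gamma (0.09), class II (−0.03), cytotoxic (0.10), dendritic (0.23), lymph node macrophage (0.12) and mast cell (0.26). Without ContraImplant day 7 replicate 1 they were monocyte (0.17), adipocyte (0.20), type I interferon (0.39), dendritic (0.17) and lymph node macrophage (0.23), and without replicate 2 tissue-resident macrophage (0.02), endothelial (−0.06), class II (−0.02), lymph node macrophage (0.15) and mast cell (0.32). Without ContraImplant day 7 replicate 3 they were muscle (0.46), interferon-gamma (0.13) and germinal centre B cell (0.01). Without Implant day 14 replicate 2 they were monocyte (0.17), tissue-resident macrophage (0.04), type I interferon (0.08), interferon-gamma (0.04), lymph node macrophage (0.01) and mast cell (0.26). Without Implant day 7 replicate 2 they were monocyte (0.20), tissue-resident macrophage (0.12), class II (−0.08), lymph node macrophage (0.10) and mast cell (0.34), and without replicate 3 lymph node macrophage (0.19). Without ContraImplant day 14 replicate 1 they were monocyte (0.23), tissue-resident macrophage (0.19) and lymph node macrophage (0.18), and without Implant day 14 replicate 1 class II (−0.07) and dendritic (0.30).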

How the results depend on the processing

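The settings with the adipocyte covariate, with adipocyte and muscle covariates, without muscle and mitochondrial genes, with animal 8 left out and with RST day 14 replicate 3 and day 21 replicate 2 both left out were tests chosen only after the results were seen. Unless the setting's own construction shows it, the cause was not tested. Of the named genes' calls, 989 kept their side and direction with DESeq2, 1000 with its size factors, 996 with no filter, 837 with the compared groups alone (141 lost) and 6985 with a library left out (1080 lost). No named gene that was called changed direction in any setting run. List tests were repeated only for lists past the preset camera, so none of them can come out stronger, and DESeq2 gives no list tests. With an estimated correlation 4 list calls were kept and 289 lost. DESeq2's size factors moved no median of all genes by over 0.1 and no split of higher against lower by over 10 points. Of genes changed 2-fold in simulated counts 58.2 to 79.1% were called in the comparisons simulated. Depth, spread and number of libraries were not separated in this.

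With DESeq2 the counts were 783 for RST against LST day 35, 1218 for RST day 14 to 21, 1216 for day 21 to 35, 734 and 2437 for Implant against NoImplant on days 7 and 14, 1113 and 11 for Implant against ContraImplant, 23 for ContraImplant against NoImplant on day 14, 53 for Implant day 7 to 14, 791 for NoImplant day 7 to 14 and 5 for the interaction with Implant against NoImplant. With no filter they were 751 for day 35, 570 for day 14 to 21, 1139 for day 21 to 35, 55 for Implant against NoImplant and 231 for Implant against ContraImplant on day 7, and 23 for NoImplant day 7 to 14. With only the compared groups, which leaves fewer libraries to estimate the spread, they were 915 for day 35, 0 for day 14 to 21 and for day 21 to 35, 1105 and 620 for Implant against NoImplant on days 7 and 14, 0 and 136 for Implant against ContraImplant, 178 for Implant day 7 to 14 and 0 for NoImplant day 7 to 14.

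Like-numbered RST and LST day 35 libraries deviated together at r = 0.08, 0.14, 0.09 and 0.19. The highest r with another number was 0.12, 0.07, 0.07 and 0.07. Same-mouse nodes had r from 0.11, so pairing stays open. NoImplant nodes came from other mice. With the replicate number as a block the counts were 557 for day 35 (1221 with these groups alone, 433 shared with the 479), 372 for day 14 to 21 and 2 for Implant against NoImplant on day 7. The block gives no value for Implant or NoImplant day 7 to 14, where animals are nested in the day. For Implant against ContraImplant on day 7, paired by animal, the block gave 19 (14 among the 131), and 297 with animal 8 left out (78 among the 131). On day 14 and for the interaction the count was 0 with or without it, and all 38 list calls were kept. With RST day 14 replicate 3 and day 21 replicate 2 left out the counts were 2611 for day 21 against LST, 5565 for day 14 to 21 and 56 for day 21 to 35, and without muscle and mitochondrial genes 475 for day 35.

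With the adipocyte covariate the counts were 12 and 0 for Implant against NoImplant on days 7 and 14, 1196 for Implant against ContraImplant on day 7, 5 for ContraImplant against NoImplant on day 7, 74 for Implant day 7 to 14 and 112 for NoImplant day 7 to 14. With adipocyte and muscle covariates they were 17, 0, 1218, 2, 35 and 0 in the same order. Covariates built from a list remove most of that list's own difference by construction, and some list tests turned. With the adipocyte covariate the medians were 0.08 (adipocyte, Implant against NoImplant day 14), 0.05 (adipocyte) and −0.01 (B cell, both Implant against ContraImplant day 14), 0.26 (adipocyte, Implant day 7 to 14), and 0.24 and −0.04 (adipocyte, interactions with NoImplant and ContraImplant). With both covariates they were 0.32, 0.12 and 0.04 for muscle in Implant against NoImplant day 7, Implant against ContraImplant day 7 and NoImplant day 7 to 14, and −0.11 and −0.17 in the interactions. For adipocyte they were 0.04, 0.08 and 0.29 in Implant against NoImplant day 14, Implant against ContraImplant day 14 and Implant day 7 to 14, and 0.05 and 0.03 in the interactions. In Implant against ContraImplant day 14 they were 0.13 for endothelial and −0.01 for B cell, and in the interaction with ContraImplant −0.07 for interferon-gamma and −0.34 for germinal centre B cell.

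With single libraries left out the counts ranged from 2502 to 4937 for RST day 21 and 182 to 544 for day 35 against LST, 2 to 4466 for day 14 to 21 and 35 to 1884 for day 21 to 35, and stayed within 1.5 times for the other joint comparisons. In nodes they were 0 to 4 and 0 to 1557 for Implant against NoImplant on days 7 and 14, 0 to 2030 and 0 to 1 for Implant against ContraImplant, 0 for ContraImplant against NoImplant, for Implant day 7 to 14 and for the interactions, and 0 to 327 for NoImplant day 7 to 14.

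Some list tests turned direction without 1 library, and their lowest and highest medians over the libraries left out follow. Without NoImplant day 7 replicate 3, type I interferon turned for Implant against NoImplant day 7 (−1.51 to 0.25), ContraImplant against NoImplant day 7 (−1.28 to 0.36), NoImplant day 7 to 14 (−1.18 to 0.53) and the interaction with NoImplant (−0.03 to 1.57), and interferon-gamma for Implant against NoImplant day 7 (−0.35 to −0.02). Without NoImplant day 7 replicate 2 muscle turned for ContraImplant against NoImplant day 7 (−2.27 to 1.26). Without ContraImplant day 7 replicate 2 these were mitochondrial genes for Implant against ContraImplant day 7 (−1.03 to 0.02), endothelial genes for ContraImplant against NoImplant day 7 (−0.17 to 0.44) and, in the interaction with ContraImplant, tissue-resident macrophage (0.02 to 0.48) and endothelial genes (−0.06 to 0.56). Without ContraImplant day 7 replicate 3 they were cell cycle for ContraImplant against NoImplant day 7 (−0.25 to 0.65) and germinal centre B cell in the interaction with ContraImplant (0.01 to 0.81), and without ContraImplant day 14 replicate 3 T cell for ContraImplant against NoImplant day 14 (−0.19 to −0.02). A test ranks the list against all other genes, so its direction may turn while the median keeps its sign.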
